A study of Mus musculus with 26 samples.

How the data were processed

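Supporting cells are the non-sensory cells that surround the hair cells of the cochlea. Per the labels, cochleae of mice at postnatal day 1 were cultured with DAPT, an inhibitor of the protease gamma-secretase that blocks Notch signalling, or with its solvent DMSO, then dissociated with trypsin and sorted. RNA was measured at 24 h in cells sorted for GFP driven by Lfng, in 3 DAPT and 3 DMSO samples. At 48 h supporting cells were marked by a TdTomato reporter (TdT) recombined by Lfng-CreER, and a GFP reporter of Atoh1 separated DAPT-treated cells that carried it (permissive) from those that did not (nonpermissive). Control cells at 48 h came from DMSO cultures and carried TdT without Atoh1-GFP. RNA at 48 h comprised 2 control, 3 nonpermissive and 3 permissive samples. Open chromatin (ATAC, Tn5 insertion into nuclei) and the histone mark H3K27ac (CUT&RUN) were each measured at 48 h in 2 samples per group. Per the labels, the RNA libraries were made with a poly(A) kit at 24 h and with a single-cell kit at 48 h, so time, sort and library kit cannot be told apart. For this reason 24 h and 48 h were fitted separately, except in the interaction tests described below. The labels do not say that replicates come from separate animals, so the p-values measure the spread between these samples, which may be technical.

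The RNA values are expected counts per gene from RSEM, as deposited, 1 table per sample. TPM is also deposited in these tables; it was looked at and not tested. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used for RNA, on the mouse build mm10; versions and settings are not given in the sources used here. The peak lists, 1 per sample, hold for each peak its deposited fold enrichment (the ratio of signal to local background) and its deposited −log10 p-value and −log10 q-value. Bowtie2, MACS2 and, for H3K27ac, UMI-tools are named in the submitters' processing notes, without roles or settings. Of 48709 gene identifiers, 48349 (99.3%) matched a symbol, and 63 symbols belonged to more than 1 identifier. At most 0.068% of a library's counts lay on identifiers without a symbol.

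Expected counts were rounded, genes with low counts were removed with filterByExpr, and libraries were scaled by TMM. The quasi-likelihood (QL) test of edgeR 4.0.16 in R 4.3.3 gave a log2 fold change, its standard error (SE) and a two-sided p per gene. Adjusted p is Benjamini-Hochberg over the genes tested in a comparison, and a gene rose or fell where it was under 0.05. The comparisons were DAPT against DMSO at 24 h, and permissive against control, nonpermissive against control and permissive against nonpermissive at 48 h, where all 8 libraries shared 1 fit. CPM, the count relative to the TMM-scaled library size, is given as mean ± SD. Where every library of a group held 0 counts of a gene, its fold is a lower bound computed with 3 counts per library. With 1 to 3 counts in a group, CPM levels or the ratio with its 95% counting interval are given. Intervals and bounds cover counting error and nothing else.

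The 27 gene lists (Notch, hair cell, supporting cell, other cell type, cell cycle, stress, signalling and metabolic genes), the tests and the rule for named genes were fixed before the data were examined. Each list was compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 27 lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. At the preset correlation camera also passed lists in other sample splits, as given below. Fry tests whether a list's genes move one way, whatever other genes do. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes higher or lower at 24 h were tested as 2 lists in each 48 h comparison, adjusted over 6 tests. Effects of 11 genes at 24 h and 48 h were compared by an interaction term in edgeR.

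Named genes were chosen in each comparison by rule. They are the 6 largest rises and 6 largest falls among genes with adjusted p under 0.05, mean log2 CPM of at least 4, no overlap between the libraries of both groups and a curated symbol. To these come up to 4 members of each list with the smallest adjusted p under 0.05. Atoh1, Pou4f3, Gfi1, Hes5, Hey1, Hey2, Lfng, Jag1, Sox2, Cdkn1b and Myo7a were always included. Members that moved against the rest of their list, further members named where few passed, and cell cycle and endothelial genes named at 48 h outside this rule were chosen after their values were seen; their calls were not refitted without single libraries. The results of a few genes are not reported here.

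Same-numbered permissive and nonpermissive 48 h samples deviated together from group means (7484 genes). For replicates 1, 2 and 3 r was 0.58, 0.15 and 0.13. All 3 were over 0.1 and were read as pairs. The labels do not say what they share. Nonpermissive 3 with permissive 2 gave 0.19, so only pair 1 stands apart. Values at 48 h with the number as a block are given where they change a call.

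Peaks on chromosomes 1 to 19 and X were reduced to unique intervals and merged, within an assay, into regions wherever they overlapped by 1 bp (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, bedtools 2.31.1). A region was gained or lost where both libraries of a group and neither library of the other held a peak. The peak names in the H3K27ac list of nonpermissive replicate 1 carry replicate 2's name although the values of both lists differ, so which nonpermissive list is which replicate is uncertain. The highest fold enrichment of an H3K27ac list was 2590 to 17000, and no control track is given in the sources used here. With 2 libraries per group the gained and lost regions are counts without a test. The other splits of the same 4 libraries are given beside them and are no baseline. The Jaccard index (shared length over total length) was compared within and between groups by an exact test over the 15 ways to pair 6 libraries. Each region was given to the nearest of 21631 protein-coding genes within 100 kb of its gene body. The annotation used carries no strand, so distance to the gene body was used in place of distance to the transcription start. The share of genes with a gained or lost region was compared between genes higher and lower in RNA by two-sided Fisher's exact tests, adjusted over 12 tests. Fixed lists were compared with 10000 random lists matched on the number of regions per gene by a two-sided permutation test, adjusted over 108 tests. Shares of regions have 95% Wilson intervals. At named genes, regions within 20 kb of the gene body were counted.

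Mitochondrial genes took 2.35 to 3.03% of counts at 24 h and 3.16 to 27.6% at 48 h. The biological coefficient of variation was 0.151 at 24 h and 0.539 at 48 h. Of 50 simulated genes changed 4-fold in each comparison, the test called 100% at 24 h. It called 18, 28 and 46% in the 48 h comparisons in the order above, so an uncalled 48 h gene is not shown unchanged. With 200 genes changed, 19 of 210 calls at 24 h and 4 of 87, 9 of 106 and 14 of 131 at 48 h were false. List, count and interval computations were also simulated, and 11 of 11 interval checks passed.

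Alternatives tried were RLE scaling, DESeq2 1.42.0, no filter on low counts, a minimum of 1 CPM, a replicate block, fits of 2 groups alone, a threshold of 0.01 and leaving out each library; a lone control library is then assumed to vary like the other groups. For regions they were a −log10 q of at least 5, peak lists of equal length, 50% of a region covered, 50 kb in place of 100 kb and single libraries. Chosen after seeing the data were library sizes without mitochondrial genes, CT010467.1 and Lars2, and 48 h fits without replicate 1 of every group. The list tests without single libraries and the use of equal-length peak lists for lists and for nonpermissive shares were also chosen then. Sequence motifs in regions were not analysed here, since the sequence of the genome was not used. Figures were drawn with matplotlib 3.10.9.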

Results

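The series holds 26 samples of sorted mouse cochlear supporting cells. RNA was sequenced in 14 of them, 6 at 24 h and 8 at 48 h, open chromatin (ATAC) in 6 and H3K27ac, a histone mark of active promoters and enhancers, in 6. RNA libraries held 10666000 to 13158859 counts at 24 h and 2165340 to 4896371 at 48 h. Spearman correlations between replicates were 0.978 to 0.993 at 24 h and 0.803 to 0.859 at 48 h. ATAC peak lists held 86988 to 170910 peaks and H3K27ac lists 46148 to 114527, each with 2 samples per group. Sequencing depth behind the peak lists is unknown. CPM is mean ± SD and log2 fold change ± SE.

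The comparison at 24 h asked how supporting cells respond to a block of Notch signalling. With DAPT, Notch target transcripts were lower and hair cell transcripts higher in sorted cells. Hes5, a transcriptional repressor induced by Notch, was at 6.32 ± 2.96 CPM with DAPT and 1710 ± 149 CPM with DMSO (SD, n = 3 each), 273-fold lower. Pou4f3, a transcription factor needed for hair cell survival, was at 1380 ± 167 CPM with DAPT and 169 ± 9.18 with DMSO, 8.16-fold higher. In all, 1742 of 15174 genes rose and 2158 fell, 673 and 970 of them at least 2-fold. Without DAPT replicate 1, the number of changed genes went from 3900 to 2573.

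Of 13 measured Notch pathway genes, 10 fell and 0 rose at 24 h, 11 and 0 adjusted over the list alone (camera adjusted p = 7.21e-30, median log2 fold change −2.28). Besides Hes5 (−8.09 ± 0.31, edgeR adjusted p = 1.35e-06), the feedback inhibitor Nrarp fell by 4.06 ± 0.13 on the log2 scale (8.05e-07). The repressors Heyl and Hey1 fell by 3.7 ± 0.18 (3.94e-06) and 2.62 ± 0.12 (3.47e-06), and Hey2 by 1.38 ± 0.14 (0.000167). Lfng, a glycosyltransferase that modifies Notch receptors, fell by 2.28 ± 0.18 (3.76e-05). Its promoter drove the sort GFP, so DAPT may have changed the cells sorted. Jag1, a Notch ligand of supporting cells, fell by 1.09 ± 0.12 (0.000259).

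Of the 7 genes listed as Notch ligands of the hair cell lineage, 6 rose, 7 adjusted over the list alone (camera adjusted p = 2.29e-39). Dll1, Dll3 and Jag2 encode ligands, and Dll3 rose by 4.51 ± 0.15 on the log2 scale (edgeR adjusted p = 8.05e-07). The other 3 that rose are Hes6, a transcription factor, Mfng, which modifies Notch receptors, and Dlk2, a membrane protein related to the ligands. Hes6 went from 108 ± 5.76 to 1380 ± 39.6 CPM.

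Hair cell transcription factors rose together, 13 of 16 with DAPT (camera adjusted p = 4.27e-27, median 1.62), with the same counts adjusted over the list alone. Insm1, a zinc finger factor of outer hair cells, rose by 5.59 ± 0.18 (edgeR adjusted p = 8.05e-07). Atoh1, the factor that starts hair cell development, rose by 3.25 ± 0.11 (8.05e-07), and Gfi1 by 1.60 ± 0.22 (0.000929). Ikzf2 was the 1 member that fell, by 0.74 ± 0.17 (0.0141). With an estimated correlation, these factors and both Notch lists kept an adjusted p of 0.0187, and no other list passed at 24 h.

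Of 50 hair cell bundle, synapse and cytoskeleton genes, 28 rose and 0 fell, 29 and 0 adjusted over the list alone (camera adjusted p = 6.02e-12; adjusted p = 0.523 with an estimated correlation). Rasd2, a small GTPase, rose by 2.31 ± 0.15 (edgeR adjusted p = 1.40e-05). Slc26a5, the motor protein prestin, rose from 0.823 ± 0.160 to 11.6 ± 4.58 CPM. Myo7a, a bundle myosin, rose by 1.22 ± 0.31 (0.0189), and its adjusted p was 0.0543 to 0.0802 without DMSO replicate 1 or 2 or DAPT replicate 1 or 2. Synaptic vesicle and excitability genes rose in 12 of 26 cases, 13 adjusted over the list alone (camera adjusted p = 0.000894; adjusted p = 0.560 with an estimated correlation), led by Snap25 (1.88 ± 0.13), and Syt1 fell by 0.96 ± 0.21. Of 21 microtubule and cilium genes 7 rose, 8 adjusted over the list alone, Kif19a by 1.33 ± 0.19 and Tekt1 by 1.14 ± 0.20. Their camera adjusted p was 0.0292 (adjusted p = 0.549 with an estimated correlation) and 0.0674 without DAPT replicate 2.

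Supporting cell markers fell at the same time. Among 20 Pillar and Deiters cell markers 12 fell and 2 rose, 12 and 3 adjusted over the list alone (camera adjusted p = 6.47e-07; adjusted p = 0.432 with an estimated correlation). The protease Prss23 went from 1180 ± 12.4 to 164 ± 41.6 CPM, and Pdzk1ip1 fell by 4.75 ± 0.25 (edgeR adjusted p = 5.19e-06). Cryab, a small heat shock protein, and Lgr5, a Wnt co-receptor, rose by 1.33 ± 0.11 and 0.74 ± 0.13. Of 11 inner phalangeal and border cell markers 9 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.393 with an estimated correlation). Fabp7, a fatty acid binding protein of glia, fell by 4.47 ± 0.32, while Cdh4 and S100a6 rose by 1.42 ± 0.11 and 1.94 ± 0.24. Of 20 pan-supporting cell and prosensory markers 14 fell and 1 rose, with the same counts adjusted over the list alone. Their camera adjusted p was 4.67e-06 (adjusted p = 0.411 with an estimated correlation). Sox2 and Sox9, transcription factors of the prosensory domain, fell by 1.09 ± 0.13 and 1.27 ± 0.12. Cdkn1b, the cell cycle inhibitor p27Kip1, fell by 0.91 ± 0.18 (0.00632).

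Extracellular matrix and tectorial membrane genes fell in 10 of 17 cases, 10 adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.411 with an estimated correlation), with the cartilage collagen Col2a1 going from 7120 ± 190 to 4410 ± 357 CPM. Markers of the epithelial ridges and of Hensen and Claudius cells fell in 5 of 17 cases and 1, Hmgn2 (0.32 ± 0.09), rose, the same adjusted over the list alone. Nupr1 fell by 5.13 ± 0.24 and Fgf10 by 0.88 ± 0.09. Their camera adjusted p was 0.0366 (adjusted p = 0.523 with an estimated correlation), and 0.326 without DAPT replicate 3. Immediate early and stress genes fell in 10 of 21 cases, 12 adjusted over the list alone, and Btg2 rose by 0.45 ± 0.11. Fos fell by 0.78 ± 0.13 and Jun by 0.78 ± 0.15. Their camera adjusted p was 0.0173 (adjusted p = 0.585 with an estimated correlation) and reached 0.0827 without DMSO replicate 3 or DAPT replicate 3.

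Markers of other cell types moved in both directions at 24 h, and 1 of 6 such lists passed. Of 5 melanocyte and stria markers 4 fell, 5 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.411 with an estimated correlation), among them the potassium channel Kcnj10, by 1.16 ± 0.20. Mesenchyme markers had 2 rises and 3 falls among 11, the same adjusted over the list alone (camera adjusted p = 0.0633; down to 0.00757 without DMSO replicate 1 or 2 or DAPT replicate 1). Lum rose by 0.99 ± 0.12 and Pdgfrb fell by 4.31 ± 0.21. Schwann and satellite glia markers had a median of −0.48 and a mean of 0.01 with 1 rise and 2 falls among 8, 1 and 3 adjusted over the list alone (camera adjusted p = 0.513). Gfra3 rose by 4.34 ± 0.45 and Erbb3 fell by 0.61 ± 0.09. Spiral ganglion neuron markers had a median of −0.36 and a mean of 0.20, with camera pointing up (adjusted p = 0.591). Of these 9, 2 rose and 1 fell, the same adjusted over the list alone. Elavl4 rose by 2.84 ± 0.25 and Prox1 fell by 0.53 ± 0.11. Of 2 measured blood and macrophage markers Laptm5 rose by 2.13 ± 0.27 (camera adjusted p = 0.266; 0.036 without DMSO replicate 3). The edgeR test called 0 of 2 endothelial markers (camera adjusted p = 0.513), 1 at an unadjusted p under 0.05 and 0 by DESeq2. Cell cycle genes had 5 rises and 1 fall among 22, the same adjusted over the list alone (camera adjusted p = 0.190), with Ccnd1 up by 0.76 ± 0.16 and Mcm6 down (−0.45 ± 0.13).

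Genes outside the lists were among the largest changes at 24 h. Sstr2, a somatostatin receptor, rose by 5.05 ± 0.10 on the log2 scale (edgeR adjusted p = 1.12e-07), and Tph1, an enzyme of serotonin synthesis, by 5.43 ± 0.27 (4.18e-06). Pmaip1 and Gadd45g, which respond to cell stress, rose by 5.36 ± 0.28 and 4.93 ± 0.21. Nos1, a nitric oxide synthase, fell by 5.67 ± 0.24 (2.06e-06), Daam2, a regulator of Wnt signalling, by 5.79 ± 0.20 (8.05e-07), and Cysltr2, a leukotriene receptor, had a log2 fold change of −7.79 ± 0.66 (6.08e-05).

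**Figure D1:**
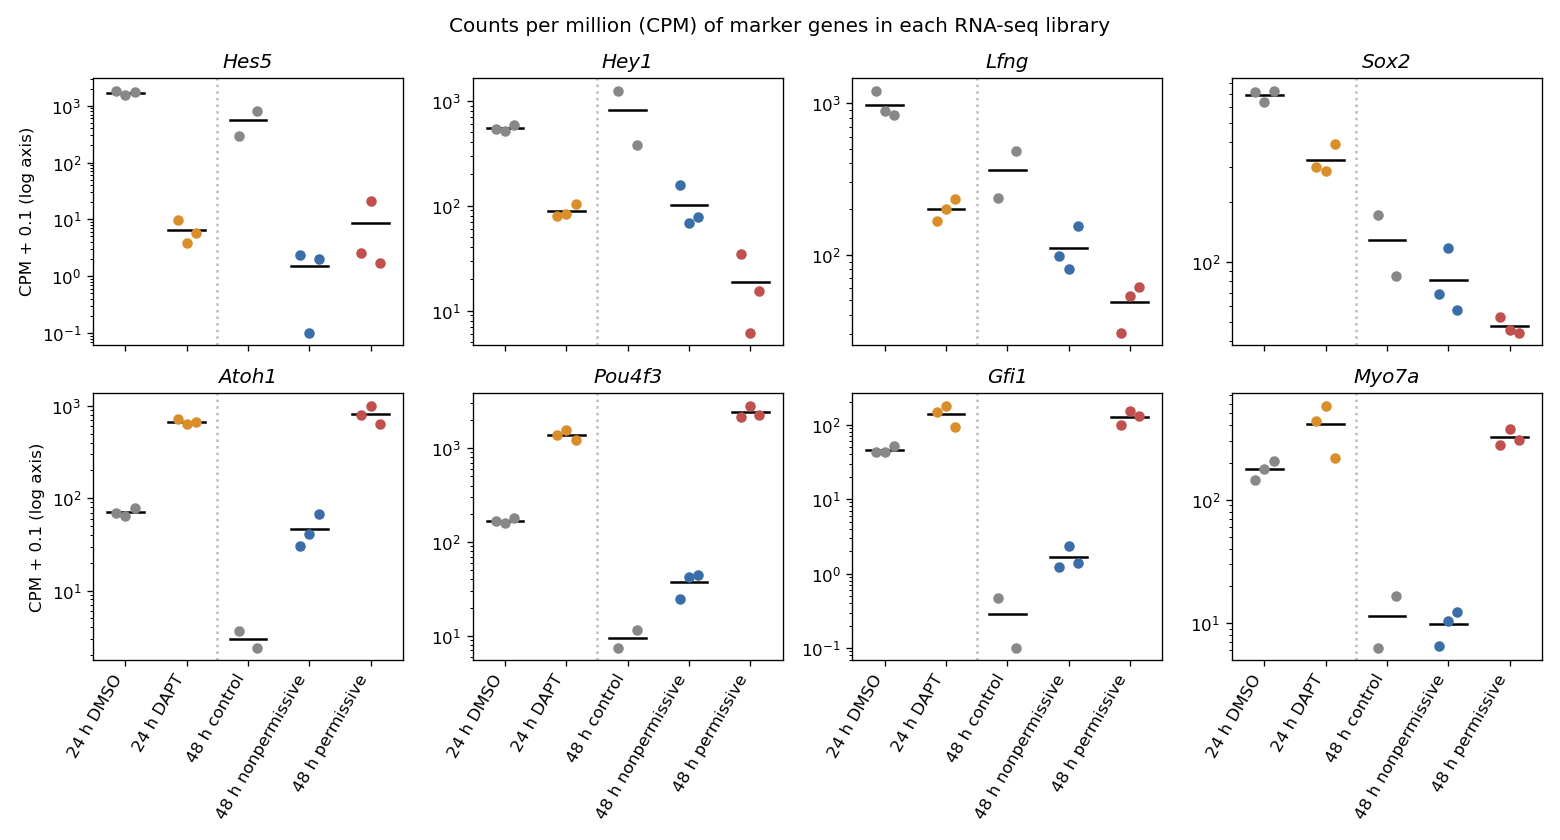
Each point is 1 RNA library and each black line a group mean, in CPM plus 0.1 on a log axis, for 8 genes in the 24 h DMSO and DAPT groups and the 48 h control, nonpermissive and permissive groups. Pou4f3 had a mean of 9.35 CPM in control, 37.0 in nonpermissive and 2430 in permissive cells, and Hey1 812, 101 and 18.8.

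The comparison of permissive with control cells at 48 h asked what distinguishes DAPT-treated supporting cells that switched on the Atoh1 reporter from untreated ones. Permissive cells had high levels of hair cell genes that were low or absent in control cells, and low levels of Notch, supporting cell and matrix genes. Pou4f3 was at 2430 ± 364 CPM (n = 3) against 9.35 ± 2.91 (n = 2), and Tecta, a tectorial membrane protein, at 169 ± 62.3 against 6720 ± 2590. Of 13411 genes, 767 rose and 976 fell. The sum of 1743 was 1066 without control replicate 1 and 1086 without control replicate 2.

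Hair cell transcription factors rose in 12 of 16 cases, 13 with 1 fall adjusted over the list alone (camera adjusted p = 3.96e-21). Their median log2 fold change was 7.91, or 7.40 with members absent from a group at their bound. Atoh1, whose reporter defined the permissive gate, was at 815 ± 187 against 2.92 ± 0.898 CPM, a check of the sort. Pou4f3 rose by 8.02 ± 0.63 (edgeR adjusted p = 3.17e-05), and Barhl1, a homeobox factor, was at least 284-fold higher. Gfi1 went from 0.187 ± 0.264 to 126 ± 26.7 CPM. Of 48 bundle, synapse and cytoskeleton genes 39 rose and 0 fell, 46 and 0 adjusted over the list alone (camera adjusted p = 5.02e-48). Myo7a rose by 4.82 ± 0.60 (0.000235), Cdh23, a tip link cadherin, by 8.93 ± 0.93 (8.67e-05), and Calb2, a calcium buffer, by 7.34 ± 0.64 (3.63e-05). Chrna10, a subunit of the efferent acetylcholine receptor, was at least 177-fold higher. Both lists kept an adjusted p of 0.00538 with an estimated correlation.

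All 7 genes listed as hair cell lineage Notch ligands rose, with the same count adjusted over the list alone (camera adjusted p = 1.40e-12; 0.0328 with an estimated correlation). Dlk2 rose by 9.22 ± 1.03 (edgeR adjusted p = 0.000111) and Dll1 was at least 132-fold higher. Synaptic vesicle and excitability genes rose in 13 of 25 cases and Syt1 fell (−1.70 ± 0.44), 18 and 2 adjusted over the list alone (camera adjusted p = 4.55e-11). Nrxn3, a synaptic adhesion protein, rose by 3.55 ± 0.48 (0.000339), and Scg3, a granule protein, was at least 124-fold higher. Microtubule and cilium genes rose in 11 of 19 cases, 15 adjusted over the list alone (camera adjusted p = 4.55e-11). Ccdc40, needed to assemble motile cilia, rose by 5.68 ± 0.91 (0.00113), and Foxj1, the regulator of motile cilia genes, went from 0.0935 ± 0.132 to 43.1 ± 9.38 CPM. Other large rises were Scn11a, a sodium channel subunit (404 ± 34.9 against 0.0935 ± 0.132 CPM), and Kcnmb2, a potassium channel subunit (at least 154-fold).

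Notch pathway genes fell in 10 of 12 cases, 11 adjusted over the list alone (camera adjusted p = 4.96e-14, median −3.39). Hes5 fell by 6.05 ± 0.96 (edgeR adjusted p = 0.00104), Hey1 by 5.42 ± 0.74 (0.00039), Jag1 by 3.4 ± 0.41 (0.000211) and Lfng by 2.90 ± 0.49 (0.00163). Hey2 fell by 3.07 ± 0.62 (0.00481), with an adjusted p of 0.0655 without control replicate 1. Among 20 Pillar and Deiters markers 10 fell and Cryab rose (2.27 ± 0.63), 11 and 1 adjusted over the list alone (camera adjusted p = 1.36e-07). Gjb2 and Gjb6, the gap junction proteins of the cochlear epithelium, fell by 4.19 ± 0.50 (0.000176) and 4.09 ± 0.58 (0.000525). Inner phalangeal and border cell markers fell in 7 of 12 cases, 7 with 1 rise adjusted over the list alone (camera adjusted p = 7.01e-05). The glutamate transporter Slc1a3 fell by 2.88 ± 0.45 (0.000969). These 3 lists passed with an estimated correlation, at adjusted p of 0.0139, 0.0085 and 0.0245.

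Of 20 pan-supporting cell and prosensory markers 10 fell, 12 adjusted over the list alone (camera adjusted p = 2.23e-10; adjusted p = 0.0671 with an estimated correlation). Tecta and Otog, proteins of the tectorial and otolithic membranes, fell by 5.31 ± 0.56 and 3.38 ± 0.40. Cdkn1b fell by 2.98 ± 0.62 (edgeR adjusted p = 0.00611). Sox2 was at 47.2 ± 4.61 against 128 ± 61.5 CPM, which did not pass (0.0602), and without control replicate 2 it did (0.0428). Extracellular matrix and tectorial membrane genes fell in 15 of 17 cases, 16 adjusted over the list alone (camera adjusted p = 8.53e-18; 0.00538 with an estimated correlation), Col11a1 by 3.96 ± 0.48 (0.000202). Ridge, Hensen and Claudius markers had 5 falls and 3 rises among 18, 8 and 3 adjusted over the list alone. Ccn2, a matricellular protein, fell by 4.21 ± 0.55, and Stmn3, Lmo3 and Calb1 rose by 5.81 ± 1.14, 4.63 ± 1.13 and 3.77 ± 1.08. Camera gave this list an adjusted p of 0.00913 (adjusted p = 0.110 with an estimated correlation), which reached 0.0533 without control replicate 2 or permissive replicate 1. Stress genes fell in 7 of 18 cases, 10 adjusted over the list alone (camera adjusted p = 9.14e-07; adjusted p = 0.0936 with an estimated correlation), with Fos at −2.10 ± 0.40 and Nr4a1 at −2.82 ± 0.47.

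Markers of other cell types differed between these libraries. Mesenchyme markers had a median of 121 CPM in control replicate 2 and 15.1 CPM in control replicate 1. Against control, 2 of 13 fell, 5 adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.308 with an estimated correlation), and without control replicate 2 camera gave 0.480. The 2 that fell were Pdgfrb (−3.29 ± 0.90) and Emilin2 (−3.95 ± 0.94). Without single libraries Pdgfrb lost its call for control replicates 1 and 2 and permissive replicates 1 and 2 (edgeR adjusted p = 0.0572 to 0.0932), and Emilin2 for control replicate 1 (0.0586). Of 10 endothelial markers 2 rose, 4 adjusted over the list alone (camera adjusted p = 0.00461; adjusted p = 0.255 with an estimated correlation), Kdr by 5.01 ± 0.98, with an adjusted p of 0.0501 without control replicate 1, and Pecam1 by 2.61 ± 0.78, with 0.0774 with the replicate block and 0.0584 to 0.230 without any 1 of control replicates 1 and 2, nonpermissive replicates 1 and 3 and permissive replicates 1 and 3. Schwann and satellite glia markers fell in 1 of 8 cases, 3 adjusted over the list alone (camera adjusted p = 0.00563; adjusted p = 0.0671 with an estimated correlation), Erbb3 by 2.91 ± 0.45. Without control replicate 1 camera gave 0.0554. Melanocyte and stria markers fell in 3 of 5 cases, 3 adjusted over the list alone (camera adjusted p = 0.00742; adjusted p = 0.0671 with an estimated correlation), Kcnj10 by 4.47 ± 0.60. Among 8 blood and macrophage markers Laptm5 rose (3.12 ± 0.81; adjusted p = 0.146 without control replicate 1 and 0.0565 without permissive replicate 3), the same count adjusted over the list alone, and the median was −1.77 (camera adjusted p = 0.207; 0.0193 without control replicate 1). Spiral ganglion neuron markers had a median of −1.11, a mean of 0.13 and camera pointing down (adjusted p = 0.615). Of these 9, Nefm rose, from 0.0935 ± 0.132 to 26.9 ± 11.4 CPM, and Stmn2 fell by 2.59 ± 0.54, the same adjusted over the list alone.

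Cell cycle genes were higher as a list in permissive cells (median 1.22, camera adjusted p = 0.000509; 0.0328 with an estimated correlation). Of 29 members 2 rose, the same adjusted over the list alone, Cdk1 by 3.76 ± 0.86 and Mcm2 by 2.13 ± 0.56 (edgeR adjusted p = 0.0103 and 0.0225). Cdk1 had an adjusted p of 0.0547 without control replicate 1 and 0.0898 without control replicate 2. Mcm2 had 0.0665 and 0.211 without these, and 0.0624 without permissive replicate 3. In the order control replicates 1 and 2, then permissive replicates 1, 2 and 3, the median CPM of the list was 5.42, 6.28, 17.3, 20.4 and 13.3.

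Nonpermissive cells had been in the same DAPT treatment without switching on the Atoh1 reporter, and the comparison with control asked what DAPT changed in them. Hes5 was at 1.38 ± 1.21 CPM (n = 3) against 555 ± 364 (n = 2), 349-fold lower, while most supporting cell genes did not pass the test in either direction. Of 13411 genes 9 rose and 17 fell. This count of 26 ranged from 2 without nonpermissive replicate 3 to 40 without permissive replicate 1. DESeq2 called 156 genes, and 986 had an unadjusted edgeR p under 0.05.

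Notch pathway genes fell in 2 of 12 cases, 7 adjusted over the list alone (camera adjusted p = 8.53e-16; 0.0215 with an estimated correlation, median −1.66). Hes5 fell by 8.45 ± 1.10 (edgeR adjusted p = 0.00647; 0.0559 without nonpermissive replicate 3) and Heyl had a log2 fold change of −3.79 ± 0.63 (0.0267; 0.0632 to 0.139 without any 1 of the 5 control and nonpermissive libraries). Hey1 had a log2 fold change of −3.0 ± 0.67 and did not pass with edgeR (0.139) but did with DESeq2 (0.00203), with the replicate block (0.0118) and without permissive replicate 1 (0.0449). Lfng (−1.71 ± 0.48, 0.273), Hey2 (−1.68 ± 0.60, 0.488) and Jag1 (−0.80 ± 0.40, 0.712) did not pass. Nos1 fell by 5.76 ± 0.72 (0.00569) with every library left out in turn. Syt6, a synaptotagmin, fell by 7.25 ± 0.87 (0.00569; 0.0551 without nonpermissive replicate 3).

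Of 7 genes listed as hair cell lineage Notch ligands, 1 rose and 6 adjusted over the list alone (camera adjusted p = 2.49e-11; adjusted p = 0.0784 with an estimated correlation). Dlk2 rose by 5.24 ± 0.93 (edgeR adjusted p = 0.0391; 0.0655 with the replicate block). Its adjusted p was 0.0777 to 0.229 without control replicate 1 or 2 or nonpermissive replicate 1 or 3. Dll1 was at 20.2 CPM against 0 in control (0.0704). Hair cell transcription factors rose in 1 of 16 cases, 3 adjusted over the list alone (camera adjusted p = 3.38e-06; adjusted p = 0.0599 with an estimated correlation). Atoh1 was at 46.2 ± 19.0 against 2.92 ± 0.898 CPM, 15.4-fold higher (0.0127), although both groups were sorted as negative for its reporter. Its adjusted p was 0.069 without control replicate 1, 0.166 without control replicate 2 and 0.0559 without nonpermissive replicate 3. Pou4f3 had a log2 fold change of 1.98 ± 0.48, not passing with edgeR (0.171) and passing with DESeq2 (0.00969). Bundle, synapse and cytoskeleton genes rose in 1 of 48 cases, 6 adjusted over the list alone (camera adjusted p = 6.62e-09; adjusted p = 0.0599 with an estimated correlation). Calb2 rose by 3.25 ± 0.55 (0.0267) and had an adjusted p of 0.0574 to 0.217 without any 1 of the 5 control and nonpermissive libraries. Myo7a was at 9.62 ± 2.92 against 11.4 ± 7.34 CPM (0.978).

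Cell cycle genes were higher as a list (median 1.63, camera adjusted p = 5.77e-18; 0.0102 with an estimated correlation). The edgeR test called 0 of 29 over all genes, 13 rose adjusted over the list alone, 15 had an unadjusted p under 0.05, and DESeq2 called 7. Ccnb1, a mitotic cyclin, was at 43.6 against 4.22 CPM (edgeR adjusted p = 0.171), and Mki67, a proliferation marker, at 38.4 against 7.01 (0.361). Endothelial markers were higher in the same libraries (median 3.23, camera adjusted p = 4.39e-16; adjusted p = 0.0599 with an estimated correlation). Of 10, 1 rose over all genes and 8 adjusted over the list alone. Kdr, a VEGF receptor, went from 0.522 ± 0.473 to 37.8 ± 24.1 CPM (0.0266), with an adjusted p of 0.0707 to 0.151 without control replicate 1 or 2 or nonpermissive replicate 1 or 3.

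Supporting cell lists moved by less. Pan-supporting cell markers had a median of −0.54 (camera adjusted p = 0.00379; adjusted p = 0.409 with an estimated correlation; 0.516 without control replicate 1). Of these 20, edgeR called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Inner phalangeal and border markers had a median of −0.48 (camera adjusted p = 0.0199; adjusted p = 0.216 with an estimated correlation and 0.0614 with the replicate block; up to 0.0896 without control replicate 1 or nonpermissive replicate 1). Of these 12, edgeR called 0, 3 fell adjusted over the list alone, 4 had an unadjusted p under 0.05 and DESeq2 called 1. Ridge, Hensen and Claudius markers had a median of 0.34 (camera adjusted p = 0.0281; adjusted p = 0.262 with an estimated correlation; up to 0.382 without control replicate 1 or nonpermissive replicate 1). The edgeR test called 0 of 18, 2 had an unadjusted p under 0.05 and DESeq2 called 0. Microtubule and cilium genes had a median of 0.94 (camera adjusted p = 0.0281; adjusted p = 0.156 with an estimated correlation; up to 0.292 without control replicate 1, control replicate 2 or nonpermissive replicate 3). Of these 19, edgeR called 0, 1 adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 0. Mesenchyme markers had a median of −1.90 (camera adjusted p = 0.00346; adjusted p = 0.439 with an estimated correlation), and pointed up without control replicate 2 (0.366). Of these 13, edgeR called 0, 2 fell adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 1.

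Several lists of cell types and functions did not pass in nonpermissive cells. Camera adjusted p was 0.168 for Pillar and Deiters markers, of which 4 of 20 fell adjusted over the list alone. It was 0.206 for Schwann and satellite glia, 0.321 for blood and macrophage (0.0291 without nonpermissive replicate 2), 0.374 for spiral ganglion neuron, 0.593 for stress and 0.342 for matrix genes. Melanocyte and stria markers had a median of −0.07, a mean of 0.61 and camera pointing up (0.984). Synaptic genes had a median of 0.25, a mean of 0.45 and camera pointing down (0.881). Across the 14 lists without a call and without a passing camera test, edgeR called 0 of 197 listed members, 22 had an unadjusted p under 0.05 and DESeq2 called 3. Sox2 (−0.67 ± 0.47) and Cdkn1b (−0.85 ± 0.60) did not pass either (edgeR adjusted p = 0.864 and 0.863).

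**Figure D2:**
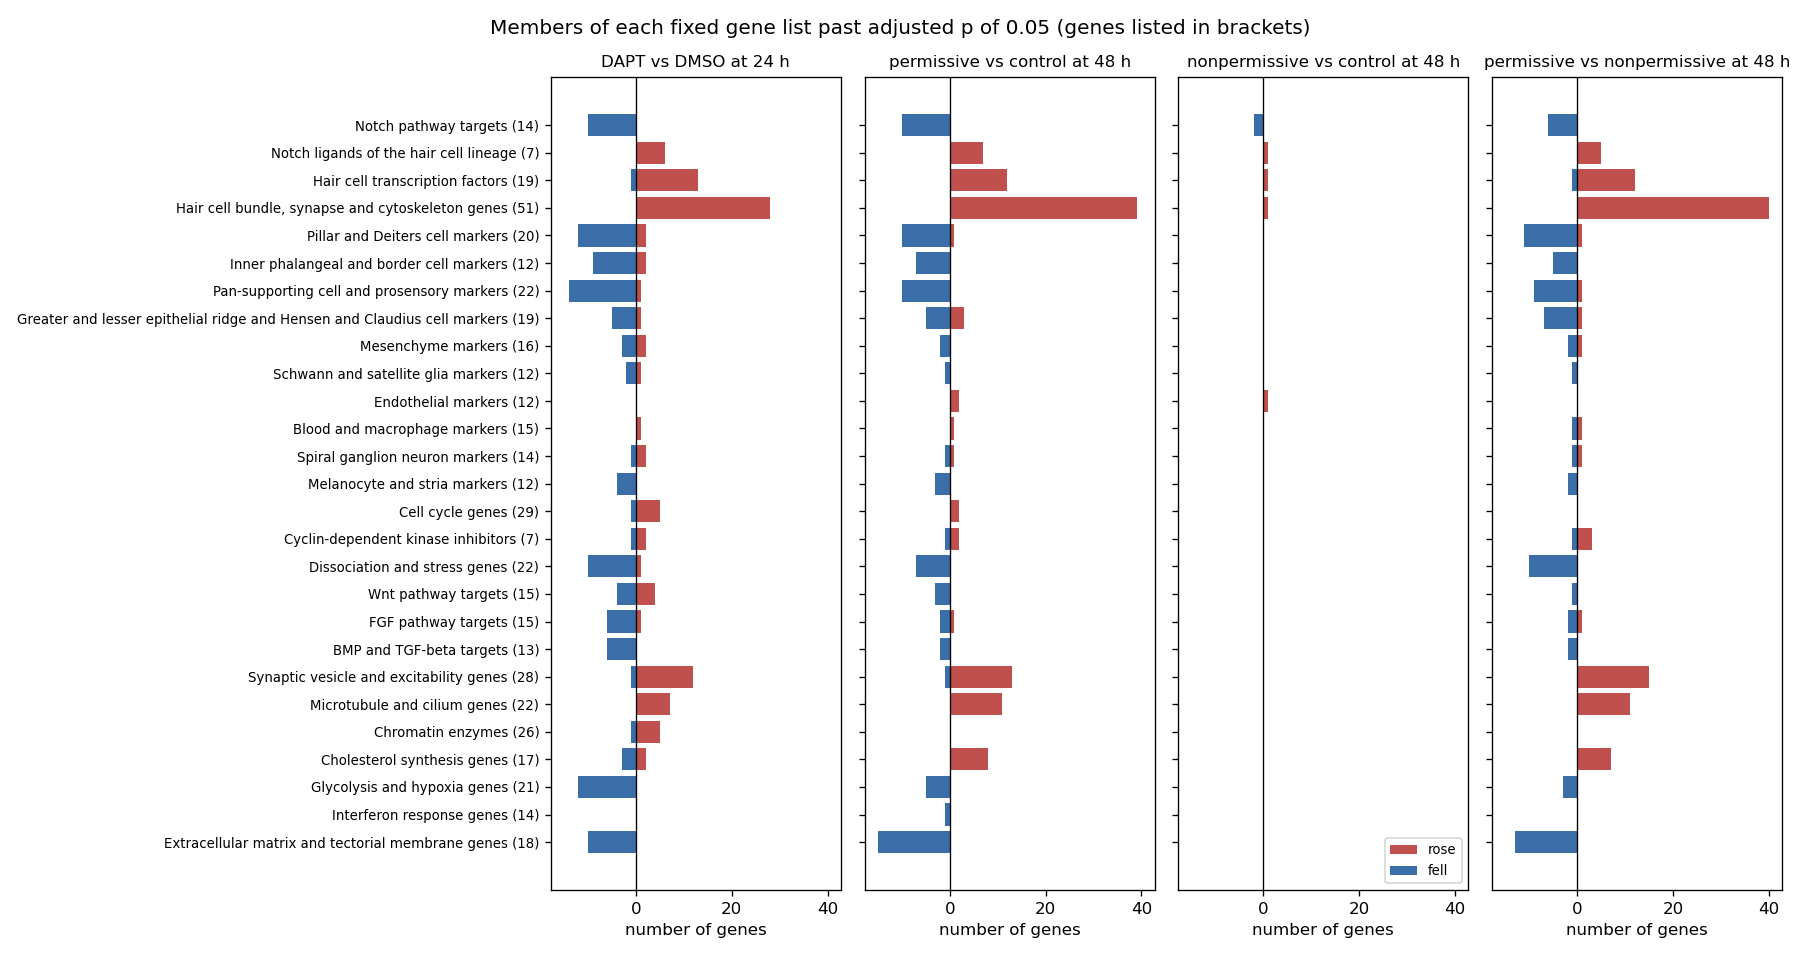
Bars count the members of each fixed list that rose (right, red) or fell (left, blue) past an edgeR adjusted p of 0.05 in each of the 4 RNA comparisons. Brackets give the number of genes listed, of which not all were measured. Bundle, synapse and cytoskeleton genes had 28 rises at 24 h, 39 in permissive against control, 1 in nonpermissive against control and 40 in permissive against nonpermissive cells.

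Permissive and nonpermissive cells shared the DAPT treatment and differed in the Atoh1 reporter. Permissive cells were higher in hair cell genes and lower in Pillar and Deiters cell and matrix genes. Myo7a was at 319 ± 48.6 CPM against 9.62 ± 2.92 (n = 3 each), and Tectb, a tectorial membrane protein, at 1540 ± 541 against 14600 ± 1340. Of 13411 genes, 909 rose and 852 fell, 1761 in all, and 979 without replicate 1 of every group.

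Of 16 hair cell transcription factors 12 rose and Ikzf2 fell (−2.69 ± 0.63), the same adjusted over the list alone (camera adjusted p = 1.39e-20; 0.00392 with an estimated correlation). Their median was 5.52, or 4.85 with bounds. Pou4f3 rose by 6.04 ± 0.48 (edgeR adjusted p = 2.50e-05), Lhx3, a LIM homeobox factor, by 7.61 ± 0.72 (5.41e-05), and Gfi1 by 6.38 ± 0.62 (6.81e-05). Atoh1, the gate, was 17.6-fold higher. Bundle, synapse and cytoskeleton genes rose in 40 of 48 cases and 0 fell, 45 and 0 adjusted over the list alone (camera adjusted p = 1.25e-48; 0.00392 with an estimated correlation). Myo15, a myosin of stereocilia tips, rose by 7.74 ± 0.72 (4.74e-05) and Cdh23 by 9.01 ± 0.79 (3.67e-05). Synaptic and excitability genes rose in 15 of 25 cases, 19 adjusted over the list alone (camera adjusted p = 4.66e-15; 0.00392 with an estimated correlation), Atp2b2, a calcium pump, by 6.94 ± 0.81. Microtubule and cilium genes rose in 11 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 1.83e-10; 0.00433 with an estimated correlation), Kif19a by 2.97 ± 0.51.

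Hes5 did not pass between these groups, at 8.39 ± 11.0 CPM in permissive and 1.38 ± 1.21 in nonpermissive cells (edgeR adjusted p = 0.125). Notch pathway genes fell in 6 of 12 cases, 8 with 1 rise adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.0877 with an estimated correlation). Jag1 fell by 2.59 ± 0.38 (0.000665) and Notch3 by 3.0 ± 0.70 (0.0116; 0.0629 without replicate 1 of every group). Hey1 fell by 2.41 ± 0.63 (0.0219), with an adjusted p of 0.0856 without nonpermissive replicate 1, 0.0704 without permissive replicate 2 and 0.0603 without permissive replicate 3. Hey2 (−1.39 ± 0.56, 0.128) and Lfng (−1.19 ± 0.44, 0.0988) did not pass. With the replicate block both did, at −1.46 (0.0432) and −1.23 (0.0354). The hair cell lineage ligand list rose in 5 of 7 cases, 6 adjusted over the list alone (camera adjusted p = 1.22e-07; adjusted p = 0.0570 with an estimated correlation), Jag2 by 3.97 ± 0.71 (0.00223).

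Of 20 Pillar and Deiters markers 11 fell and Cryab rose (1.72 ± 0.53), the same adjusted over the list alone (camera adjusted p = 1.26e-06; 0.0119 with an estimated correlation). Gjb2 fell from 1010 ± 124 to 60.6 ± 27.1 CPM. Inner phalangeal and border markers fell in 5 of 12 cases, 6 adjusted over the list alone (camera adjusted p = 0.00212; adjusted p = 0.0570 with an estimated correlation). Trpm3, a cation channel, fell by 3.24 ± 0.38 and Slc1a3 by 2.57 ± 0.42. Of 20 pan-supporting cell markers 9 fell and Cldn14, a tight junction protein, rose (2.42 ± 0.55), the same adjusted over the list alone (camera adjusted p = 5.10e-07; adjusted p = 0.110 with an estimated correlation). Sox2 did not pass (−0.78 ± 0.43, edgeR adjusted p = 0.292), and Cdkn1b fell by 2.13 ± 0.58 (0.0257), with an adjusted p of 0.0624 to 0.121 without nonpermissive replicate 1, permissive replicate 2 or 3, or replicate 1 of every group. Ridge, Hensen and Claudius markers fell in 7 of 18 cases and Stmn3 rose, 9 and 3 adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.0538 with an estimated correlation), with Otoa at −3.6 ± 0.62. Matrix and tectorial membrane genes fell in 13 of 17 cases, 14 adjusted over the list alone (camera adjusted p = 1.02e-17; 0.00433 with an estimated correlation). Stress genes fell in 10 of 18 cases, 11 adjusted over the list alone (camera adjusted p = 1.26e-06; adjusted p = 0.110 with an estimated correlation), with Atf3 at −3.26 ± 0.51.

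Cell cycle genes did not pass as a list between permissive and nonpermissive cells (median −0.69, camera adjusted p = 0.122). The edgeR test called 0 of 29, also adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 2. Endothelial markers were lower in permissive cells (median −1.12, camera adjusted p = 0.0286; adjusted p = 0.358 with an estimated correlation; up to 0.144 without nonpermissive replicate 3 or permissive replicate 1). The edgeR test called 0 of 10, 3 had an unadjusted p under 0.05 and DESeq2 called 0. Schwann and satellite glia markers fell in 1 of 8 cases, Erbb3 by 2.84 ± 0.43, and 2 adjusted over the list alone. Their camera adjusted p was 0.0309 (adjusted p = 0.178 with an estimated correlation), up to 0.146 without control replicate 1 or 2, nonpermissive replicate 1 or permissive replicate 1 or 2. Melanocyte and stria markers fell in 2 of 5 cases, with Kcnj10 at −4.13 ± 0.57, the same adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.0570 with an estimated correlation). Pmel was at least 10.5-fold lower. Mesenchyme markers had 1 rise and 2 falls among 13, the same adjusted over the list alone (camera adjusted p = 0.0989; 0.0317 with the replicate block, down to 0.000706 without nonpermissive replicate 2 or permissive replicate 3), Lum falling by 4.68 ± 0.87. Emilin2 also fell (−2.98 ± 0.89, 0.0394), a call lost with the replicate block (0.0589) and without control replicate 1, nonpermissive replicate 1 or 3 or permissive replicate 1 or 3 (0.0519 to 0.126). Blood and macrophage markers had 1 rise, Laptm5 (2.69 ± 0.67), and 1 fall, C1qc (−4.65 ± 1.07), among 8, 1 and 2 adjusted over the list alone (camera adjusted p = 0.0811; 0.0414 with the replicate block, down to 0.0132 without control replicate 1 or 2, nonpermissive replicate 2 or permissive replicate 2 or 3). Spiral ganglion markers had a median of −0.31, a mean of 0.52 and camera pointing up (adjusted p = 0.891), with 1 rise (Nefm) and 1 fall (Stmn2) among 9, 1 and 2 adjusted over the list alone. With single libraries left out, Stmn2 kept its call for permissive replicate 2 alone (0.0503 to 0.155 without each other library). Laptm5 lost its call without nonpermissive replicate 1 or 2 or permissive replicate 3 (0.0628 to 0.0656), and C1qc without nonpermissive replicate 3 (0.0981).

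The genes that changed at 24 h were followed into the 48 h groups, which share no library with them. Of 1637 genes higher with DAPT at 24 h, 89.0% had a positive log2 fold change in permissive against control cells (median 1.29, camera adjusted p = 9.21e-39), and 63.6% in nonpermissive against control cells (median 0.22, 1.56e-05). Of 1910 genes lower at 24 h, 91.6% were negative in permissive cells (median −1.57, 2.34e-49) and 75.2% in nonpermissive cells (median −0.43, 2.26e-16). In permissive against nonpermissive cells, 85.2% of the former were positive (1.25e-34) and 83.9% of the latter negative (8.83e-27). All 6 tests passed with an estimated correlation, at adjusted p of 0.000116 to 0.00519.

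In open chromatin and H3K27ac, the groups at 48 h were compared by the presence of peaks. The 6 ATAC lists merged into 361941 regions, 24804 of them (6.85%) found in all 6 libraries, and the H3K27ac lists into 232378, 8310 of them (3.58%) in all. Permissive against control cells had 11596 gained and 8831 lost ATAC regions, and 9145 gained and 4014 lost H3K27ac regions. The other 2 splits of the same libraries gave sums of 5783 and 17840 for ATAC and 5034 and 6582 for H3K27ac, below those of the groups. Permissive against nonpermissive cells had 11451 gained and 7700 lost ATAC regions (other splits 6187 and 17103). For H3K27ac they had 6748 gained and 5487 lost, below the higher of the other splits (3268 and 15765). Nonpermissive against control cells had 4111 gained and 4942 lost ATAC regions (other splits 7043 and 14037), and 4067 gained and 918 lost H3K27ac regions (other splits 6209 and 8486). These splits are no baseline, since regions that part the groups cannot count in them and longer lists raise their counts. Whether the sums exceeded them depended on the setting. At a −log10 q of at least 5 the permissive sums were below the higher other split, and with equal-length lists above it. Gained and lost H3K27ac regions were then 5087 and 5006 against control, and against nonpermissive cells the balance turned, to 4326 and 6459. The smaller of both directions, compared after the data were seen, was above that of the other splits in every setting, which is no test. In the other splits it was at most 1259, 1191 and 3382 for ATAC and 883, 1255 and 675 for H3K27ac, in the order above. The mean Jaccard index was 0.314 within and 0.292 between groups for ATAC (exact p = 0.133) and 0.175 and 0.161 for H3K27ac (exact p = 0.400). The smallest p the 15 pairings can give is 0.0667, so the test decides nothing.

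**Figure D3:**
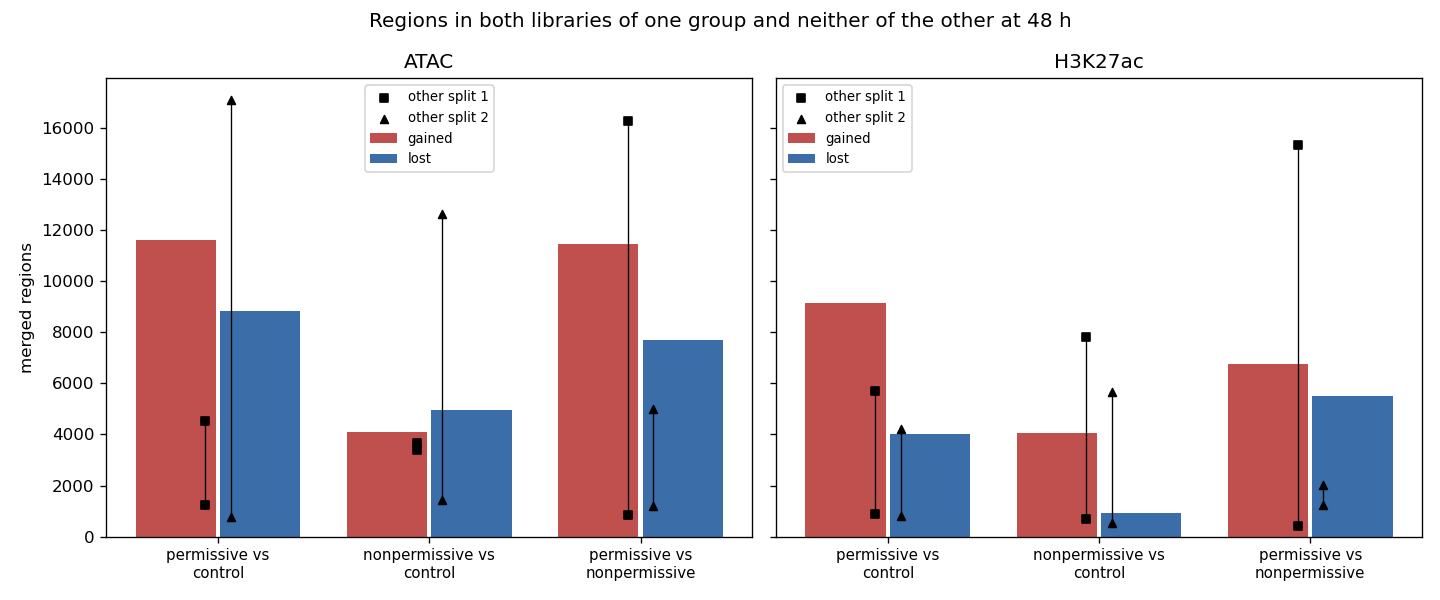
Bars are the numbers of ATAC and H3K27ac regions gained and lost in each 48 h comparison (2 libraries per group), and squares and triangles joined by a line are both directions of the other 2 splits of the same 4 libraries. Permissive against control cells had 11596 gained and 8831 lost ATAC regions.

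Regions gained in permissive cells were mostly without a peak in nonpermissive cells. Of 11596 ATAC regions gained against control, 4.85% (95% interval 4.47 to 5.25) had a peak in both nonpermissive libraries and 75.1% in neither. Of 8831 lost ATAC regions, 35.3% were in both nonpermissive libraries and 30.3% in neither. For H3K27ac, 8.17% of gained regions were in both and 65.1% in neither, and 44.7% of lost regions were in both and 14.2% in neither. ATAC regions found in both libraries of a group overlapped H3K27ac peaks of both libraries in 30.5% of cases in control, 35.9% in nonpermissive and 35.8% in permissive cells. With equal-length lists these shares were 29.9, 36.2 and 30.5%. Of ATAC regions gained in permissive cells, 24.8% overlapped permissive and 5.27% control H3K27ac. Of lost ones, 8.61% overlapped permissive and 21.1% control H3K27ac.

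Gained and lost regions lay near the genes that changed in RNA. In permissive against control cells, 68.1% of 700 higher genes had a gained H3K27ac region within 100 kb, against 27% of 893 lower genes and 30.6% of uncalled genes (Fisher's exact test, higher against lower, adjusted p = 4.80e-61). A lost H3K27ac region lay near 8.14% of higher, 47.3% of lower and 14.5% of uncalled genes (6.32e-70). For ATAC, gained regions lay near 63.1% of 712 higher and 43.1% of 902 lower genes (2.73e-15), and lost regions near 33.0% and 55.5% (2.90e-19). All 4 shares were above those of uncalled genes (32.9% and 28.7%). Between permissive and nonpermissive cells, a gained H3K27ac region lay near 63.9% of 823 higher and 18.6% of 784 lower genes (4.73e-78; uncalled 23.5%), and a lost one near 11.3% and 57.0% (2.05e-87; uncalled 19.0%). The ATAC shares were 61.8% and 42.1% for gained (2.73e-15; uncalled 32.1%) and 32.3% and 55.0% for lost regions (5.74e-20; uncalled 26.3%). In nonpermissive against control cells 1 of 4 such tests passed, with a lost ATAC region near 0 of 7 higher and 8 of 15 lower genes (exact adjusted p = 0.030). With peak lists of equal length its adjusted p was 0.211.

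**Figure D4:**
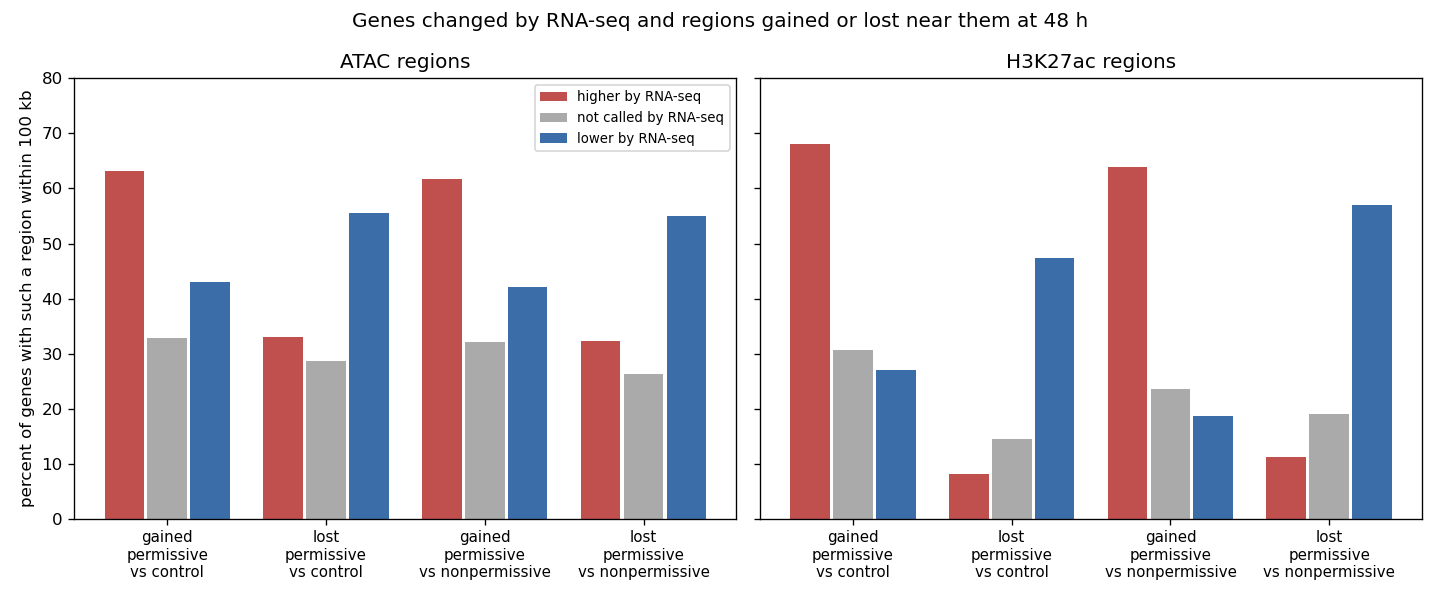
Bars are the percent of genes with a gained or a lost region within 100 kb, among genes higher, not called and lower in RNA, for permissive against control and permissive against nonpermissive cells, by assay. In permissive against control cells, 68.1% of higher and 27% of lower genes had a gained H3K27ac region.

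In permissive against control cells, hair cell genes of the fixed lists lay near gained regions more often than matched random genes. A gained H3K27ac region lay near 41 of 48 bundle, synapse and cytoskeleton genes, where matched random lists gave 19.9 (permutation test, adjusted p = 0.0072, at the smallest p the permutations give, 0.0002). It lay near 15 of 16 hair cell transcription factors (7.42 in random lists, 0.0072), 7 of 7 of the hair cell lineage ligand list (1.90, 0.011) and 17 of 25 synaptic genes (10.1, 0.045). A gained ATAC region lay near 35 of the 48 bundle genes (23.2, 0.0072) and 15 of the 16 transcription factors (8.00, 0.012). Lost ATAC regions lay near 10 of 12 inner phalangeal and border markers (4.24, 0.013), and lost H3K27ac near 7 of these (2.52, 0.043) and 10 of 18 stress genes (3.02, 0.011). Lost H3K27ac lay near 2 of 48 bundle genes, fewer than in random lists (10.7, 0.011). With equal-length peak lists the synaptic list (adjusted p = 0.13) and both inner phalangeal results (0.66 for ATAC, 0.30 for H3K27ac) no longer passed. No test of Notch pathway or Pillar and Deiters genes passed in either assay.

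Among 13 genes examined singly, gained H3K27ac regions in permissive against control cells were most numerous around Pou4f3. Within 20 kb of its gene body on chromosome 18 (42394597 to 42396093, mm10) lay 9 gained H3K27ac and 3 gained ATAC regions. The H3K27ac lists held 1 and 3 peaks there in control, 1 and 2 in nonpermissive and 14 and 17 in permissive replicates 1 and 2. Myo7a had 5 gained H3K27ac regions, Barhl1 4, Lhx3 and Rasd2 3 each, and Gfi1 2, with 0 H3K27ac peaks at Gfi1 in all 4 control and nonpermissive libraries. At Atoh1 on chromosome 6, a gained H3K27ac region (64726402 to 64735932) overlapped the gene. Another (64740661 to 64744388) overlapped a gained ATAC region (64741865 to 64742367) 10620 bp from the gene body. At Hes5 on chromosome 4, H3K27ac was lost at 154960391 to 154960768, over the gene body (154960626 to 154962372), in permissive and in nonpermissive cells against control. An ATAC region and an H3K27ac region were gained in permissive cells 6536 bp and 12032 bp from Hes5. At Hey2 on chromosome 10, ATAC regions were lost within the gene body (30837041 to 30837420) and 846 bp from it (30843629 to 30844027).

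**Figure D5:**
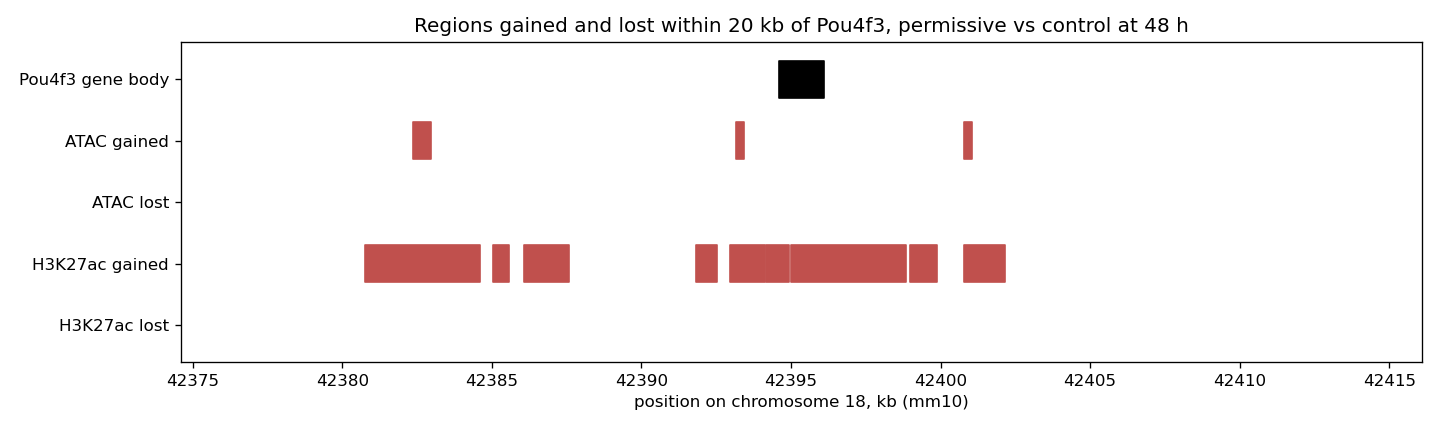
Map of chromosome 18 in kb (mm10) within 20 kb of the Pou4f3 gene body, with ATAC and H3K27ac regions gained in permissive against control cells as bars on separate tracks. The window holds 3 gained ATAC and 9 gained H3K27ac regions and no lost region.

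Single regions were chosen by the highest fold enrichment in the group that has them, 3 gained and 3 lost per assay. The gained ATAC region on chromosome 14 (79787853 to 79788434) lay 16541 bp from Pcdh8, a protocadherin gene whose RNA was higher in permissive cells (log2 fold change 10.28, edgeR adjusted p = 0.000668). A gained H3K27ac region on chromosome 2 (63058564 to 63065656) overlapped Kcnh7, a potassium channel gene (5.33, 0.0054), and another on chromosome 6 (64796029 to 64803288) lay 64784 bp from Atoh1. Lost ATAC regions on chromosome 4 lay 59592 bp (72049611 to 72050353) and 3776 bp (72105630 to 72106169) from Tle1, a co-repressor (RNA −2.58, 0.00516). A lost H3K27ac region on chromosome 19 (9141233 to 9145077) lay 5667 bp from Asrgl1 (−2.54, 0.00363). Other lost H3K27ac regions overlapped Pi4kb and Zfp687 on chromosome 3 and Rab11fip4 on chromosome 11, where RNA did not pass (0.66, 0.573 and −0.13, 0.918). The remaining 3 gained regions and 1 lost region had no gene within 100 kb.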

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

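The counts over other splits of the samples in this part were chosen after the results were seen. The interaction tests compare the effect in permissive against control cells at 48 h with that of DAPT against DMSO at 24 h for 11 genes fixed beforehand, and 8 passed. The hair cell genes differed by more on the log2 scale at 48 h. The difference (48 h minus 24 h) was 4.94 for Pou4f3 (edgeR adjusted p = 1.07e-07), 4.78 for Atoh1 (2.93e-07), whose reporter is the gate, and 3.55 for Myo7a (6.88e-05). For Gfi1 it was 7.39 (2.09e-07), an uncertain size with 0.374 and 0 CPM in the control libraries. Among genes that fell, it was −2.85 for Hey1 (0.00285), −2.37 for Jag1 (1.86e-05), −2.12 for Cdkn1b (0.00335) and −1.74 for Hey2 (0.0231). Hes5 (1.97, 0.0885), Lfng (−0.68, 0.219) and Sox2 (−0.41, 0.380) did not pass. Time, sort and library kit differ together, so these differences cannot be assigned to time. Both times shared a spread per gene despite coefficients of variation of 0.151 and 0.539, so these p-values may be too small. In nonpermissive cells none of the same 11 differences passed with edgeR, the lowest adjusted p being 0.147.

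For groups of 3 libraries each, the counts of calls were set against other splits of the same 6 libraries. For changed genes, 1 of 10 splits gave as many at 24 h (3900, highest other 0) and 1 of 10 for permissive against nonpermissive cells (1761, highest other 0). For gene lists passing camera, 2 of 10 splits gave as many at 24 h (15, highest other 15), and 1 of 10 for permissive against nonpermissive cells (20, highest other 17). The splits are too few for a share under 0.05.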

How the results depend on the processing

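Of 4731 alternative values of named genes, 4416 kept the call or its absence, 301 lost the call, 13 gained one and 1 reversed. Of 1134 values of single lists 998 did so, 100 lost the call, 34 gained one and 2 reversed. A turn of direction is counted as reversed only where the value passed before or after. All 18 alternative tests of the 24 h genes kept their call, as did 34 of 36 of regions near changed genes and 105 of 108 of fixed lists and regions. Of 36 values of single regions 29 stayed and 7 were lost, and 40 of 156 peak counts at named genes moved. Wif1 reversed without control replicate 2 in permissive against control cells (log2 fold change 1.04, adjusted p = 0.800), and was −6.57 without control replicate 1. The mesenchyme and glycolysis lists in nonpermissive cells also reversed without control replicate 2, with an adjusted p of 2.27e-10 to 0.366 and 0.000446 to 0.874 over the libraries left out. The cause was not tested.

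At an adjusted p of 0.01, changed genes numbered 2239 at 24 h, 846 for permissive against control, 5 for nonpermissive against control and 856 for permissive against nonpermissive cells, by construction fewer. For nonpermissive against control cells, DESeq2 gave 156, no filter on low counts 302 and a fit of both groups alone 49, against 26; the cause was not tested. Leaving out a library gave 2573 to 4948 at 24 h, 1066 to 1738 for permissive against control, 2 to 40 for nonpermissive against control and 1215 to 1796 for permissive against nonpermissive cells, which had 979 without replicate 1 of every group. RLE scaling (3898, 1751, 25 and 1772) and library sizes without mitochondrial genes, CT010467.1 and Lars2 (3895, 1800, 26 and 1783) stayed within 1.5 times. Lists passing fell from 70 to 25 with an estimated correlation. With the replicate block the counts were 3328, 2058, 36 and 2152. In permissive against nonpermissive cells it changed no other call of a list or named gene than those given beside the results. At 24 h same-numbered samples share only a number (r = 0.01, −0.05 and −0.07), and control has 2 pairs. In permissive against control cells the block brought the blood (0.0374) and interferon (0.0374) lists past the threshold, and Wif1 no longer passed (0.0731). At 24 h it brought the mesenchyme list past the threshold (0.0191).

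At a −log10 q of at least 5, gained and lost ATAC regions were 3625 and 3638 for permissive against control, 833 and 1508 for nonpermissive against control and 3651 and 2660 for permissive against nonpermissive cells. For H3K27ac they were 967 and 474, 1624 and 19, and 349 and 1011. Equal-length lists gave 5087 gained and 5006 lost H3K27ac regions for permissive against control and 4326 and 6459 for permissive against nonpermissive cells. With 50% of a region covered, H3K27ac gave 4314 and 1748 for permissive against control and 3237 and 3496 for permissive against nonpermissive cells. By construction stricter lists are smaller and a single library per group raises the counts. For permissive against control, nonpermissive against control and permissive against nonpermissive cells in turn, gained ATAC regions then ranged over 13144 to 90306, 5551 to 48730 and 12960 to 91097, and lost ones over 9506 to 52426, 6561 to 48725 and 8379 to 51780. Gained H3K27ac regions ranged over 11299 to 78137, 7183 to 49463 and 7261 to 67408, and lost ones over 4889 to 23484, 1196 to 17543 and 6598 to 46405. The log2 odds ratio of lost ATAC regions near changed genes in nonpermissive cells was −1.93 with equal-length lists (adjusted p = 0.211) and 0.00 with genes at 0.01 (1.0). The share of accessible regions acetylated was 29.9, 36.2 and 30.5% in control, nonpermissive and permissive cells with equal-length lists, and 29.2, 34.4 and 34.0% with 50% covered. Both motif alternatives were not run. In the simulations, depth, spread between replicates, group size and library kit differ together between 24 h and 48 h. Depth alone was not tested.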

Other observations

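In this part, the tests of mesenchymal RNA and of endothelial cells were chosen after the results were seen. Genes of growth factor signalling moved in part. Of 11 BMP and TGF-beta targets 6 fell and 0 rose at 24 h, with the same counts adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.387 with an estimated correlation). Id3, an inhibitor of helix-loop-helix factors, fell by 1.37 ± 0.10 and Bambi, a BMP pseudoreceptor, by 1.53 ± 0.17. At 48 h 2 of the 11 fell in permissive cells, Ccn1 and Ccn2, matricellular proteins, both against control (camera adjusted p = 0.00089; 0.0328 with an estimated correlation) and against nonpermissive cells (0.000249; 0.0337). The same counts held adjusted over the list alone. Against control Ccn1 had an edgeR adjusted p of 0.314 without control replicate 1 and 0.0743 and 0.108 without permissive replicates 1 and 2. For nonpermissive against control cells the median was −0.35, the mean −0.04 and camera pointed up (adjusted p = 0.826). FGF targets fell in 6 of 15 cases at 24 h and Fgfr1 rose (0.43 ± 0.11), the same adjusted over the list alone (camera adjusted p = 0.0827; 0.0481 without DMSO replicate 1). Etv4, a factor induced by FGF, fell by 1.27 ± 0.11 and Spry4, a feedback inhibitor, by 1.99 ± 0.22. At 48 h 1 rose and 2 fell in permissive cells against control (1 and 3 adjusted over the list alone, camera adjusted p = 0.0169; adjusted p = 0.236 with an estimated correlation) and against nonpermissive cells (1 and 4, 0.0309; adjusted p = 0.294). The latter reached 0.0765 without nonpermissive replicate 1 or 3 or permissive replicate 3. Fgf8 was at 18.5 ± 14.3 CPM in permissive and 0.692 ± 0.605 in nonpermissive cells. In nonpermissive against control cells the median was −0.25, the mean 0.08 and camera pointed down (adjusted p = 0.683).

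Wnt targets split at 24 h, with 4 rises and 4 falls among 13, the same adjusted over the list alone (camera adjusted p = 0.843). Nkd1, a feedback inhibitor, rose by 1.5 ± 0.14, and Fzd9, a receptor, fell by 1.95 ± 0.10. In permissive cells Tnfrsf19 fell by 2.79 ± 0.65 against control, among 3 falls (3 adjusted over the list alone, camera adjusted p = 0.0164; adjusted p = 0.0779 with an estimated correlation; 0.152 without control replicate 2). It fell by 3.99 ± 0.64 against nonpermissive cells as the 1 fall (3 and 1 rise adjusted over the list alone, camera adjusted p = 0.0367; adjusted p = 0.112 with an estimated correlation). The latter reached 0.071 without nonpermissive replicate 1 or permissive replicate 1 or 2. In nonpermissive against control cells the median was 0.15, the mean −0.55 and camera pointed down (0.535; 0.00949 without control replicate 1), with 2 falls adjusted over the list alone. Cholesterol synthesis genes rose in permissive cells in 8 of 16 cases against control, 11 adjusted over the list alone (camera adjusted p = 4.98e-06; 0.0235 with an estimated correlation). Against nonpermissive cells 7 of 16 rose, 11 adjusted over the list alone (1.41e-05; 0.0297 with an estimated correlation). Fdft1, squalene synthase, rose by 2.45 ± 0.47 against control, and Sqle, squalene epoxidase, by 1.80 ± 0.38 against nonpermissive cells (edgeR adjusted p = 0.0719 without replicate 1 of every group). The list did not pass at 24 h (0.942, with 2 rises and 3 falls among 17, the same adjusted over the list alone) or in nonpermissive against control cells (0.206). Glycolysis and hypoxia genes fell in 12 of 21 cases at 24 h, 16 adjusted over the list alone (camera adjusted p = 0.00069; adjusted p = 0.560 with an estimated correlation). Aldoc, an aldolase, fell by 1.75 ± 0.12 there and by 3.89 ± 0.53 in permissive against control cells. In that comparison 5 of 21 fell, 7 adjusted over the list alone (camera adjusted p = 0.000946; adjusted p = 0.180 with an estimated correlation; 0.0558 without control replicate 2). Against nonpermissive cells 3 fell, 4 adjusted over the list alone (0.0223; adjusted p = 0.298 with an estimated correlation; up to 0.056 without nonpermissive replicate 3 or permissive replicate 1). In nonpermissive against control cells edgeR called 0 of 21, 2 had an unadjusted p under 0.05 and DESeq2 called 1. Their camera adjusted p was 0.0339 (adjusted p = 0.422 with an estimated correlation; up to 0.874 without control replicate 2 or nonpermissive replicate 1).

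Cyclin-dependent kinase inhibitors went both ways. At 24 h Cdkn2b and Cdkn1a rose, by 2.71 ± 0.28 and 1.04 ± 0.16, and Cdkn1b fell, among 5 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0949; 0.0283 without DMSO replicate 1). In permissive cells Cdkn1c, p57Kip2, rose to 254 ± 64.1 CPM from 26.0 ± 19.6 in control and 22.4 ± 7.26 in nonpermissive cells. Of 6 inhibitors 2 rose and 1 fell against control (3 and 1 adjusted over the list alone, camera adjusted p = 0.111; down to 0.028 without control replicate 2 or permissive replicate 3), and 3 rose and 1 fell against nonpermissive cells (the same adjusted over the list alone, 0.191). Between nonpermissive and control cells none passed with edgeR (camera adjusted p = 0.535; 0.0449 without control replicate 2), 1 had an unadjusted p under 0.05 and DESeq2 called 0. Chromatin enzymes had 5 rises and 1 fall among 26 at 24 h, the same adjusted over the list alone (camera adjusted p = 0.513), with Kdm1a at 0.42 ± 0.08 and Dnmt3a at −0.49 ± 0.09. At 48 h edgeR called 0 of 26 in permissive against control (camera adjusted p = 0.819; 3 at an unadjusted p under 0.05, 1 by DESeq2), nonpermissive against control (0.843; 1 and 0) and permissive against nonpermissive cells (0.747; 1 and 0). Interferon response genes were called 0 of 6 times by edgeR at 24 h (camera adjusted p = 0.557; 3 at an unadjusted p under 0.05, 0 by DESeq2). In permissive against control cells 1 of 7 fell, also adjusted over the list alone (camera adjusted p = 0.119; down to 0.00344 without control replicate 1 or permissive replicate 3). For interferon genes in nonpermissive against control cells edgeR called 0 of 7 (camera adjusted p = 0.0281; adjusted p = 0.409 with an estimated correlation; up to 0.874 without control replicate 2 or nonpermissive replicate 1 or 2), 1 at an unadjusted p under 0.05 and 0 by DESeq2. Against nonpermissive cells permissive ones had 0 of 7 called (0.747; 1 and 1).

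Mesenchyme markers were higher in control replicate 2 than in replicate 1 (median 121 against 15.1 CPM, 7.99-fold), which raised the hypothesis that mesenchymal RNA in that library accounts for genes lower in permissive than control cells. Without it, with a single control library, 667 genes were lower and 64.3% of the 976 kept their call, which argues against it as the source of those. For the mesenchyme list itself the camera adjusted p was 0.480 without that library, so RNA of mesenchymal cells may account for that list. The TdT sort would remove mesenchymal cells that lack the reporter. The difference between permissive and control cells that the design names remains open for this list and was not tested apart from it.

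Cell cycle genes were higher in nonpermissive than control cells (median log2 fold change 1.63), and dividing endothelial cells might carry that RNA. With the mean log2 CPM of endothelial markers as a covariate, the cell cycle median was 1.39 and the list passed camera. The endothelial median went from 3.23 to 1.04. The covariate parted control (0.93, 1.79) from nonpermissive libraries (3.73 to 4.69), so endothelial RNA remains open. Thinning every library to 2165340 counts left a median of 1.89, which argues against a difference in library size. In the order control replicates 1 and 2, then nonpermissive replicates 1, 2 and 3, the list's median CPM was 5.42, 6.28, 23.7, 24.6 and 31.4. The list was also higher in permissive than control cells (median 1.22) and did not pass between permissive and nonpermissive cells. Both rises rest on the same 2 control libraries. An effect of DAPT on division of supporting cells remains a hypothesis, found and tested on the same samples.

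Endothelial markers were higher in nonpermissive than control cells, 10 of 10 by mean CPM, with counts for all 10 in a control library and none of them on another fixed list. A lower share of supporting cells would raise markers of every other cell type alike, and 4 of 4 other lists had medians more than 1 below the endothelial one without control replicate 2 (endothelial 4.40, mesenchyme 0.94, Schwann −0.48, blood 1.5, melanocyte −0.17), which argues against it. Endothelial cells among the sorted nonpermissive cells may account for the pattern, and the TdT sort would remove endothelial cells without the reporter. Permissive libraries (mean log2 CPM 2.16 to 3.84) also exceeded both controls, so both rises rest on the same 2 control libraries. In control replicates 1 and 2, then nonpermissive replicates 1, 2 and 3, Cdh5 was at 8.23, 6.85, 81.0, 27.4 and 52.2 CPM, Kdr at 0.187, 0.856, 36.9, 14.3 and 62.4, and Emcn, which overlapped between the groups, at 1.31, 25.4, 17.3, 21.1 and 56.3. A change of these genes within supporting cells was not tested.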
